A study of Mus musculus with 6 samples.

How the data were processed

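RNA sequencing data of 6 Balb/c mice were used, 3 that received DMSO as vehicle and 3 that received ITSN orally at 1 mg/kg per day, with groups taken from the treatment label. Per the labels' protocols, 6 separate mice were divided at random, total RNA was isolated with TRIzol and a column kit, and libraries were made by enrichment of mRNA or removal of ribosomal RNA, fragmentation and dUTP second-strand marking, followed by PCR. Which of the 2 enrichment steps was used is not stated. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier, the annotation release and whether strand was used in counting are not given in the sources used here.

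The authors deposited a single table of FPKM per gene and library, named as FPKM per the file headers, with Ensembl gene IDs, symbols and loci. It held 13823 genes and 1 blank line, and the higher of the 2 group means was at least 0.5 FPKM for every gene, so genes under that level were not analysed here. The last ITSN column carries a number that matches that sample's description and not its title. Columns were assigned to samples by these descriptions. No read counts were used. The low values of 300 genes per library were checked for multiples of a whole read against jittered values. The periodicity was below that of jittered values in 4 libraries and above it in ITSN 2 (0.177 against 0.167) and ITSN 3 (0.177 against 0.175), and from 5.33% to 13.7% of the values lay within 0.05 of a whole number, where even spacing gives 10%. Counts were not recovered and the depth of each library is unknown. The sum of FPKM was 226109, 221885 and 216251 in vehicle 1, 2 and 3 and 207114, 207268 and 209695 in ITSN 1, 2 and 3. FPKM divides by a library's total, so a larger share of mitochondrial or ribosomal transcripts in a library lowers its other values.

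Genes with at least 1 FPKM in at least 3 libraries were tested (12257). Values were analysed as log2(FPKM + 1), so fold changes of low genes are understated. ITSN was compared with vehicle in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All adjusted p-values of genes come from limma. The test, the filter, the gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. Group values are means ± SD of FPKM over 3 libraries.

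The named genes were Tgfbr1; up to 12 genes per direction by fitted change among those that passed, with groups that did not overlap and at least 2 FPKM in the higher group mean, leaving out predicted genes, clone names, immunoglobulin and T cell receptor segments, pseudogenes and olfactory or vomeronasal receptors, with open places filled by the smallest unadjusted p; the 2 to 4 members of each described list with the smallest unadjusted p; a fixed set of TGF-β and EMT genes, of which 1 is not reported here; and 5 sex-linked genes. Since 5 named genes passed upward and 1 downward, 18 of the 24 places hold genes that did not pass. Krt8, Krt18, Mki67, Hsd17b12, Ccnb1ip1, Zfp281 and the muscle genes Acta1, Myh4 and Ttn were chosen after their values were seen.

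In all, 34 gene lists covered TGF-β signalling and targets, EMT, matrix, proliferation, p53 and apoptosis, interferon, inflammation, hypoxia and glycolysis, unfolded protein, Nrf2 and immediate early responses, lipid synthesis, oxidative phosphorylation, ribosomal proteins, cell types and sex. Lists with at least 3 tested members (30) were tested against other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Each member count was also adjusted over the list alone, which takes no account of the number of lists. The lists held 671 gene entries. Where a symbol had several IDs, the most abundant one stood for the list. The sex-linked list had 1 tested gene, Xist.

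The GC content of each gene was that of its longest transcript in GENCODE M21, matched by ID for 99.7% of genes, of which 12772 also had the same coordinates. Principal components were taken of the centred log2 values. The position of a library between the other 2 of its group was computed on the FPKM scale for genes whose end libraries differed at least 2-fold. Means of 3 against 3 libraries were compared with an exact two-sided permutation test, whose smallest p is 0.1. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

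The test was checked on simulated data for the 12257 genes, with 200 genes changed. The changed genes were drawn from the more abundant ones. Noise was independent for each gene and library, with no outlying library and no GC trend. With the spread of all 6 libraries, limma recovered 11.9% of 67 genes changed by 0.5 log2 units, 82.1% of 67 changed by 1 and 95.5% of 66 changed by 2, with 6 false calls. With the spread of the libraries without vehicle 1 these shares were 70.1%, 98.5% and 100%, with 9 false calls.

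The other settings fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, trimmed-mean scaling in the style of TMM without precision weights, quantile normalization, limma without a trend, the replicate number as a block, array weights, each library left out in turn, and added fold thresholds. After the data had been seen, removal of a GC trend from each library (loess, span 0.5), removal of mitochondrial and ribosomal RNA region genes with rescaling, leaving out vehicle 2 and ITSN 1, and leaving out vehicle 1 together with the GC removal were added. Also after the result was seen, the 9 ways to leave out 1 library of each group, the 10 splits with an estimated correlation and a gene-by-gene estimate of the array weights were run as checks. A count test on recovered reads was foreseen and not run, since reads were not recovered.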

Results

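Gene expression was measured by RNA sequencing in 6 Balb/c mice, 3 given vehicle (dimethyl sulfoxide, DMSO) and 3 given isotoosendanin (ITSN) by mouth at 1 mg/kg per day. ITSN is a plant limonoid that the series title describes as acting on TGFβR1, the type I receptor for transforming growth factor β (TGF-β), and on the epithelial-mesenchymal transition (EMT) that TGF-β induces in triple-negative breast cancer. The labels call the tissue breast and do not say whether it was tumour. The table listed 13823 genes in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), of which 11949 were protein coding. Depth is unknown, because FPKM does not keep it. The median FPKM of the listed genes was 4.20, 4.74 and 4.91 in vehicle 1, 2 and 3, and 5.12, 5.04 and 5.18 in ITSN 1, 2 and 3.

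Some epithelial and some mesenchymal transcripts stood at high levels in the tissue. In vehicle, the simple epithelial keratins Krt8 and Krt18 stood at 192 ± 46.1 and 240 ± 45.1 FPKM, and the mesenchymal genes Vim and Fn1 at 270 ± 49.0 and 397 ± 80.7 FPKM (SD, n = 3). Other epithelial genes were low, such as Cdh1 at 4.70 and Cldn7 at 1.16 FPKM in vehicle. Of 23 epithelial markers 13 reached the expression filter. Mki67, a marker of dividing cells, was at 119 ± 46.2 FPKM in vehicle and 103 ± 15.9 FPKM in ITSN (SD, n = 3 each). None of 18 B and plasma cell markers and none of 10 hepatocyte markers reached the expression filter of 1 FPKM in 3 libraries. Of 23 T and NK cell markers, 6 did. The labels state male mice, yet Xist, the transcript of the inactive X chromosome, was at 20.1, 26.8 and 29.3 FPKM in vehicle 1, 2 and 3 and at 27.5, 25.1 and 28.5 FPKM in ITSN 1, 2 and 3. Of 5 sex-linked genes looked for, Xist alone was among the listed genes. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were not listed, where every listed gene reached 0.5 FPKM in the higher group mean.

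The libraries differed in more than treatment. Vehicle 1 stood apart on the first principal component, which held 54.1% of the variance, with a score of -43.2 against scores from -4.63 to 20.1 in the other 5 libraries. The second component, with 23.7% of the variance, separated ITSN (9.64 to 12.2) from vehicle 2 and 3 (-16.0 and -22.2), but vehicle 1 lay at 5.84. Mitochondrially encoded transcripts took 32.3%, 22.4% and 17.5% of the FPKM sum in vehicle 1, 2 and 3 and 14.3%, 15.6% and 13.5% in ITSN 1, 2 and 3. Their mean share was 24.1% ± 7.54 in vehicle and 14.5% ± 1.10 in ITSN (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The noncoding genes Gm26917 and Gm42418 of the ribosomal RNA region took 2.57% ± 0.267 in vehicle and 4.63% ± 0.659 in ITSN (SD, n = 3 each, exact p = 0.1). Vehicle 2 lay between vehicle 1 and vehicle 3 for 73.2% of the tested genes, and ITSN 1 between ITSN 2 and ITSN 3 for 63.7%, where 3 unrelated values would give 33.3%. In each group the library with the highest share was taken, and genes are not independent, so 33.3% does not test these shares. A simulated library centred midway between vehicle 1 and vehicle 3, with independent noise, lay between them for 51.9%. Its noise was scaled, gene by gene, to the distance between these 2 libraries. The simulated share therefore follows from that setting and is not a measured baseline. A second simulated library, a blend with a fraction of 0.35 from vehicle 1 and the rest from vehicle 3, lay between them for 74.4%. Its fraction and its small noise were likewise chosen, so this share is no measured baseline either.

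**Figure D1:**
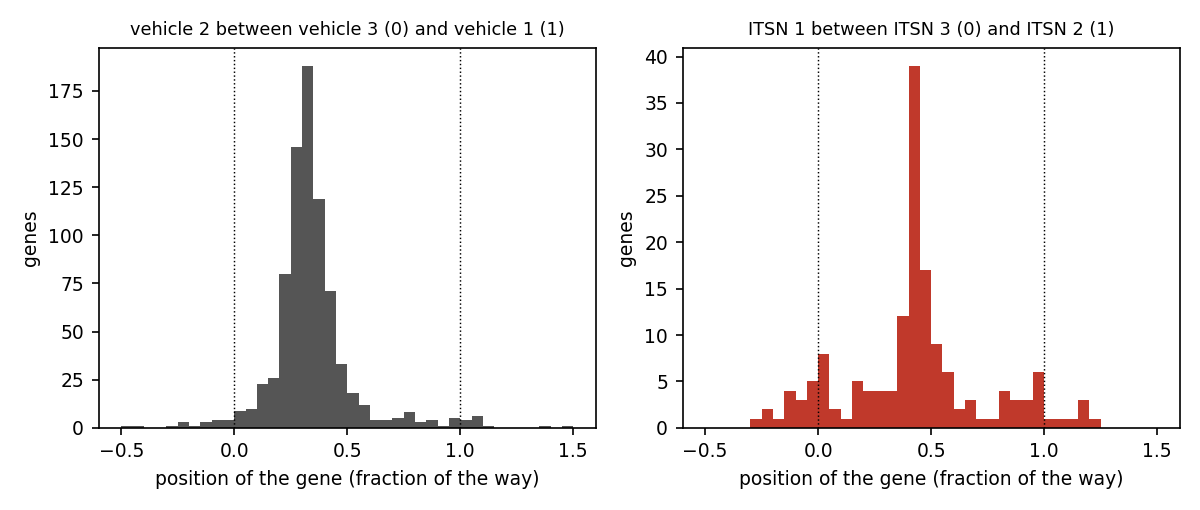
Histograms of where vehicle 2 lay between vehicle 3 (position 0) and vehicle 1 (position 1), and where ITSN 1 lay between ITSN 3 (0) and ITSN 2 (1), for the genes whose end libraries differed at least 2-fold (804 and 157 genes, of which 4 and 0 lie outside the axis). The medians were 0.319 in vehicle and 0.433 in ITSN.

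The main comparison asked which genes differ between ITSN and vehicle. At a Benjamini-Hochberg adjusted p under 0.05 in limma, 7 of 12257 tested genes changed, 6 higher and 1 lower in ITSN. Pcdhgc3, a clustered protocadherin of cell adhesion, rose from 0.818 ± 0.213 to 9.81 ± 0.411 FPKM (SD, n = 3 each). Ly6e, an interferon-inducible membrane protein, rose from 2.75 ± 0.259 to 12.7 ± 1.29 FPKM, and Wwtr1, which encodes the Hippo pathway coactivator TAZ, from 26.6 ± 1.99 to 59.3 ± 4.74 FPKM. Scand1, a SCAN domain protein, rose from 4.84 ± 1.07 to 15.0 ± 0.748 FPKM, and Lrp10, a receptor of the LDL receptor family, from 3.62 ± 0.211 to 8.12 ± 0.421 FPKM. Kirrel, an immunoglobulin-superfamily adhesion molecule, was the gene that fell, from 16.8 ± 0.238 to 7.72 ± 0.186 FPKM. For each of these 6 genes the 3 ITSN values and the 3 vehicle values did not overlap.

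On the log2(FPKM + 1) scale the limma estimate for Pcdhgc3 was 2.58 (SE 0.11, adjusted p = 0.0017) and the ratio of group means 12.0. Ly6e had a log2 change of 1.87 (SE 0.11, limma adjusted p = 0.0056) and a ratio of means of 4.63. The estimates were 1.47 for Scand1 (SE 0.14, limma adjusted p = 0.037), 1.13 for Wwtr1 (SE 0.10, adjusted p = 0.034) and 0.98 for Lrp10 (SE 0.09, adjusted p = 0.037). For Kirrel the log2 change was -1.03 (SE 0.08, limma adjusted p = 0.020). The seventh gene, AC149222.1, lies outside the rule for named genes and was chosen after its values were seen: it was listed at 0 in every vehicle library and at a mean of 2.32 ± 0.618 FPKM in ITSN (SD, n = 3, limma adjusted p = 0.032).

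In the mm10 coordinates of the table, Pcdhgc3 (ENSMUSG00000102918.1) lies on chromosome 18 at 37806364 to 37841873, where it shares exons with other members of the γ-protocadherin cluster, so that its value depends on how reads were split among them. Ly6e is on chromosome 15 at 74955051 to 74959905, Wwtr1 on chromosome 3 at 57455649 to 57575910 and Kirrel on the same chromosome at 87078593 to 87174747. Scand1, on chromosome 2 at 156311847 to 156312704, and Lrp10, on chromosome 14 at 54464137 to 54471497, have exons that overlap Cnbd2 and Gm10366 on the opposite strand, and the use of strand in counting is not given in the sources used here, so both values are uncertain. AC149222.1 has exons that overlap Hsd3b7 and Setd1a on the same strand, so that its value depends on how reads were split among them.

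**Figure D2:**
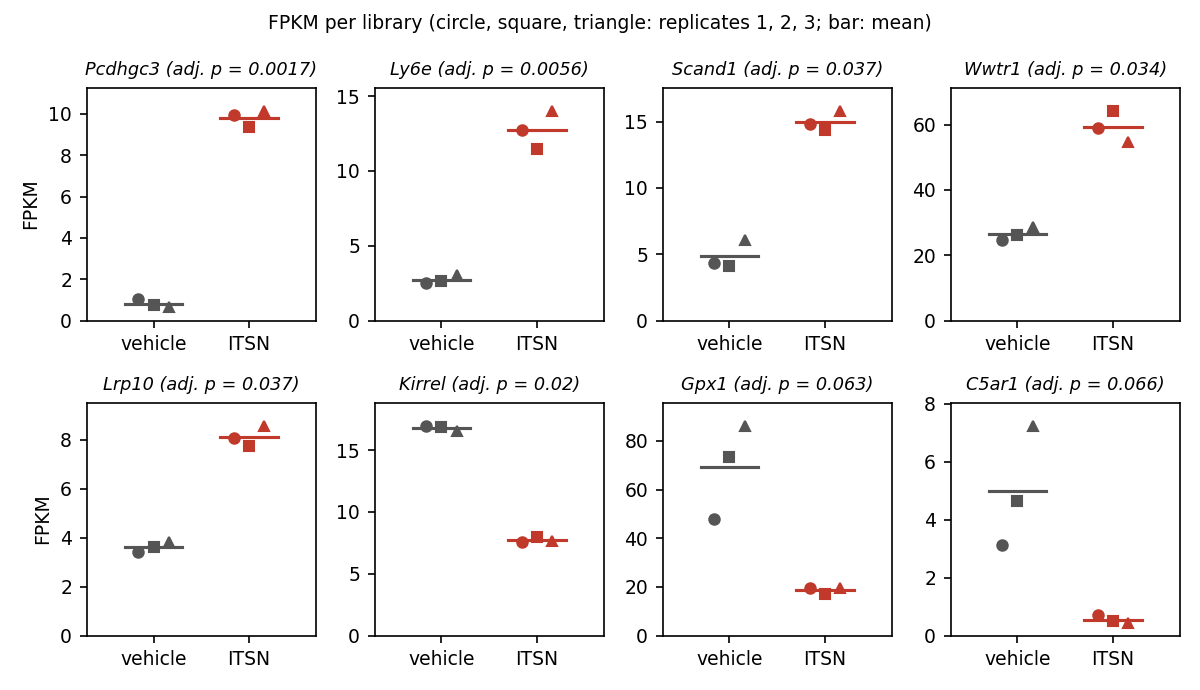
FPKM of 8 genes in each library, with vehicle in grey, ITSN in red, and a bar at the group mean. The first 6 passed an adjusted p of 0.05, and Gpx1 (0.063) and C5ar1 (0.066) did not, although their groups did not overlap.

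A wider set of genes separated the groups without passing the adjusted threshold when all 6 libraries were used without further scaling. Of the 24 genes named for their change, 6 passed there, 21 after trimmed-mean scaling, 21 after quantile normalization and 24 without vehicle 1, against 1 to 5 without any 1 of the other libraries. With the replicate number as a block 2 of them passed, and without vehicle 2 and ITSN 1 0 did. Of these 24 genes, 7 passed after removal of the GC trend described below, and 13 without both vehicle 1 and that trend. All 24 were chosen from the same data for groups that do not overlap and for a small p. That they pass in settings where more genes pass is therefore no separate evidence for these genes. Among those that were lower in ITSN were Gpx1, the cytosolic glutathione peroxidase, at 69.2 ± 19.4 in vehicle and 18.8 ± 1.43 FPKM in ITSN (log2 change -1.79, limma adjusted p = 0.063), and C5ar1, the receptor of the complement fragment C5a, at 5.00 ± 2.08 and 0.554 ± 0.137 FPKM (log2 change -1.89, limma adjusted p = 0.066; SD, n = 3 each). Without vehicle 1, after trimmed-mean scaling and after quantile normalization, limma gave an adjusted p of 0.0057, 0.020 and 0.019 for Gpx1 and of 0.023, 0.032 and 0.023 for C5ar1. The respiratory chain genes Uqcrb and Ndufs6 (log2 changes -0.65 and -0.57), the transcription factor Creb1 (-0.65) and Znrd1as (-1.04), Sfr1 (-0.74), Anp32a (-0.68), Cfdp1 (-0.56), Ap1ar (-0.66) and Sarnp (-0.49) were also lower, with limma adjusted p from 0.0508 to 0.0740. Those higher in ITSN were Snhg3 (log2 change 1.05), a host gene of small nucleolar RNAs whose exons overlap Rcc1, Scarf2 (0.90), Gnb2 (0.84), Gramd1a (0.83), Rabac1 (0.83), the class I gene H2-Q1 (0.83) and the small GTPase Rhob (0.63), with limma adjusted p from 0.0508 to 0.0626. In all, 2560 genes had an unadjusted p under 0.05, where 613 would be expected by chance, and 3569 genes (29.1%) had groups that did not overlap, where chance gives 10%. The count of 2560 was 3531 without vehicle 1, 3142 without vehicle 3, 2316 without ITSN 2, 1651 without vehicle 2, 1601 without ITSN 3, 1421 without ITSN 1 and 1687 after removal of the GC trend described below. Without both vehicle 2 and ITSN 1 it was 585, the lowest of the 9 fits that leave out 1 library of each group, which otherwise ran from 684 to 3951.

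The number of genes that passed rested on vehicle 1 and on the scaling. Without vehicle 1, limma called 673 genes, 410 higher and 263 lower, among them the 7 above. When the GC trend described below was removed as well, 59 genes passed, 19 higher and 40 lower, so the balance of directions turned. Without any 1 of the other libraries limma called from 1 (ITSN 3 left out) to 10 (vehicle 3 left out), with 2 for vehicle 2, 4 for ITSN 1 and 2 for ITSN 2. Pcdhgc3 passed whichever library was left out (adjusted p 0.00080 to 0.045), Ly6e passed in 4 of these 6 fits, Kirrel, Wwtr1, Scand1 and AC149222.1 in 2 each and Lrp10 in 1. The split was 59 higher and 49 lower of 108 genes after trimmed-mean scaling between libraries, and 62 higher and 31 lower of 93 after quantile normalization, which moved the median log2 change of all tested genes from 0.09 to -0.02 (a shift also seen with trimmed-mean scaling, to -0.01).

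Fold changes also followed the GC content of the transcripts. Across 12234 genes, which are not independent replicates, the log2 change rose with GC content with a Spearman rho of 0.59. The median log2 change was -0.09 in the decile of genes lowest in GC (median GC 38.5%) and 0.40 in the highest (59.1%). The 410 genes called higher without vehicle 1 had a median GC of 57.1%, against 42.5% in the 263 called lower and 48.6% in all tested genes. After a smooth GC trend was removed from each library, 8 genes passed in limma. Of the 7 genes above, Pcdhgc3 (log2 change 2.31, limma adjusted p = 0.010), Ly6e (1.60, 0.0066), Wwtr1 (1.16, 0.010) and Kirrel (-1.21, 0.021) still passed. Scand1 (0.77 after removal, adjusted p = 0.11), Lrp10 (0.60, adjusted p = 0.090) and AC149222.1 (1.43, adjusted p = 0.067) did not, and Gpx1 (-2.11, adjusted p = 0.010), Snhg3, Ndufs6 and the steroid dehydrogenase gene Hsd17b12 came to pass. Of the genes that were higher without passing, Scarf2, Rabac1, Gnb2, Gramd1a and Rhob had log2 changes of 0.31, 0.41, 0.43, 0.55 and 0.34 after removal. H2-Q1, at 0.83 before removal, moved less and had 0.74 after it.

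**Figure D3:**
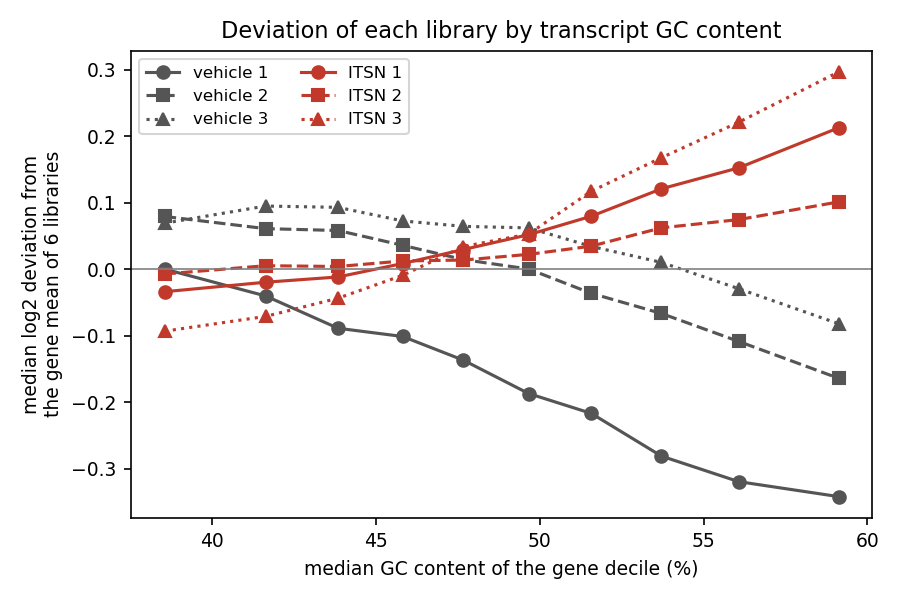
Median log2 deviation of each library from the gene's mean over the 6 libraries, for 10 equal bins of genes by transcript GC content. The 3 ITSN libraries (red) lie above the 3 vehicle libraries (grey) in the bin of highest GC content, and vehicle 1 lies lowest there.

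The question in the series title concerns TGF-β signalling and EMT. In the main comparison, with all 6 libraries, the filter of 1 FPKM and no further scaling or weights, no gene of these lists passed limma's threshold over all genes. Ltbp4 passed with a filter of 5 FPKM (adjusted p = 0.0469). Leaving out vehicle 1 let 1 TGF-β pathway component, 3 TGF-β target genes, 1 epithelial marker and 1 matrix-degrading enzyme pass, all higher in ITSN, among them Ltbp4 (limma adjusted p = 0.024), Cdkn1a (0.037), Junb (0.034) and Adam8 (0.037), and none of these passed when the GC trend was removed as well. Tgfbr1 itself, on chromosome 4 at 47353222 to 47414931, was at 30.1 ± 2.48 FPKM in vehicle and 27.7 ± 1.31 FPKM in ITSN (SD, n = 3 each, exact two-sided permutation p = 0.3). Its log2 change was -0.11 (SE 0.09, limma adjusted p = 0.54), or -0.05 without vehicle 1, -0.04 after GC removal and 0.06 with both. Vim was at 272 ± 7.47 FPKM and Fn1 at 409 ± 49.2 FPKM in ITSN (log2 changes 0.03 and 0.05, limma adjusted p = 0.94 and 0.89), and the epithelial cadherin Cdh1 went from 4.70 ± 1.20 to 6.20 ± 1.20 FPKM (log2 change 0.35, adjusted p = 0.37).

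Among the pathway genes, Tgfb1 was at 9.95 ± 0.481 FPKM in vehicle and 13.5 ± 1.23 in ITSN (log2 change 0.41, limma adjusted p = 0.10), and the inhibitory Smad gene Smad7 at 9.70 ± 1.91 and 14.3 ± 0.533 (0.53, adjusted p = 0.12; SD, n = 3 each). Smad3 had a log2 change of 0.00, which turned to -0.11 after trimmed-mean scaling and -0.04 after quantile normalization. Of the EMT transcription factors, Snai1 had a log2 change of 0.45 (limma adjusted p = 0.16), Twist1 of -0.30 (adjusted p = 0.18) and Zeb1 of -0.02 (adjusted p = 0.94), and the matrix metalloproteinase genes Mmp2 and Mmp9 of 0.45 and 0.09 (adjusted p = 0.59 and 0.91). After trimmed-mean scaling the estimates for Vim, Fn1 and Mmp9 turned to -0.08, -0.06 and -0.01. With each library left out in turn, several of these estimates went both ways: Smad3 ran from -0.25 to 0.29, Mmp2 from -0.05 to 0.82, Mmp9 from -0.24 to 0.52, Vim from -0.13 to 0.13, Fn1 from -0.08 to 0.21 and Zeb1 from -0.15 to 0.07. Cdh1 ran from 0.17 to 0.47. The values without vehicle 1 were 0.29 for Smad3, -0.05 for Mmp2, -0.04 for Mmp9 and 0.17 for Cdh1. Cdh2 and Snai2 were not among the listed genes.

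**Figure D4:**
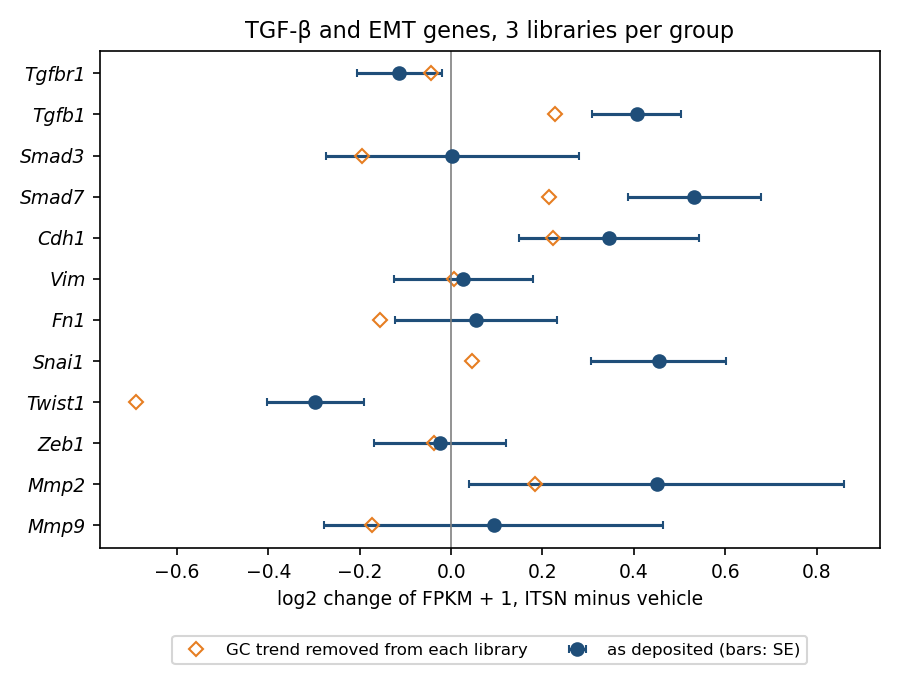
Log2 change of 12 TGF-β and EMT genes, ITSN minus vehicle, on the FPKM + 1 scale, with SE bars from limma, and the estimate after removal of a GC trend (open diamonds). Twist1 has the lowest value, -0.30, and -0.69 after GC removal.

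As lists, the TGF-β and EMT groups did not pass limma's camera test against other genes. In all, 64.0% of the tested genes were higher in ITSN, with a median log2 change of 0.09, and the list medians and counts below include that shift. After trimmed-mean scaling 49.2% were higher and after quantile normalization 46.9%. Of 22 TGF-β pathway components 17 were higher in ITSN (median log2 change 0.09, or -0.00 after trimmed-mean scaling, camera adjusted p = 0.53), with 1 gene, the latent TGF-β binding protein Ltbp4, passing when adjusted over the list alone (9.50 ± 0.627 to 16.3 ± 0.825 FPKM, log2 change 0.72, limma adjusted p over all genes = 0.063). Of 23 TGF-β target genes 16 were higher (median 0.19, camera adjusted p = 0.76), and the cell cycle inhibitor Cdkn1a (log2 change 0.58) and the AP-1 gene Junb (0.76) passed when adjusted over the list alone. Of 20 mesenchymal markers 16 were higher (median 0.20, camera adjusted p = 0.88), and of 13 epithelial markers 10 (median 0.28, camera adjusted p = 0.72); none passed when adjusted over the list alone. Without vehicle 1 the median of the mesenchymal markers turned to -0.03 and that of the epithelial markers was 0.19, with 0.14 for TGF-β target genes and 0.11 for matrix-degrading enzymes. Collagens and other matrix genes were higher for 23 of 25 (median 0.32, camera adjusted p = 0.53; 0 passed over the list alone), and of 21 matrix-degrading enzymes and inhibitors 16 were higher (median 0.17, camera adjusted p = 0.76), with Adam8 passing over the list alone (log2 change 0.56). Without vehicle 1 the TGF-β pathway components had a median of 0.22 and were higher than other genes (camera adjusted p = 0.041), a call lost with an estimated correlation (adjusted p = 0.92). That form of camera called no list with all 6 libraries or in any split of them, so the loss cannot decide whether the call holds.

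GC content and vehicle 1 moved with these lists. After the GC trend was removed, Ltbp4, Cdkn1a and Junb had log2 changes of 0.23, 0.34 and 0.26, Adam8 of 0.31, Tgfb1 and Smad7 of 0.23 and 0.21, and Snai1 of 0.04. Cdh1 and Mmp2 had 0.22 and 0.18, and Smad3, Mmp9 and Fn1 turned to -0.20, -0.17 and -0.15. In vehicle 1 the collagens and matrix genes lay a median of 1.49 log2 units below the mean of vehicle 2 and 3 (a value of -1.49, 23 of 25 lower); without vehicle 1 their median log2 change between ITSN and vehicle was -0.00.

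Genes of stress and growth control were next. Of 21 p53 targets and apoptosis genes 4 were higher when adjusted over the list alone, namely Cdkn1a, the antiapoptotic Bcl2l1 (3.07 ± 0.206 to 6.20 ± 1.28 FPKM, SD, n = 3 each), the proapoptotic Bbc3 and the stress-induced Sesn2, with log2 changes of 0.58, 0.81, 0.55 and 0.57. The list median was 0.00, or -0.10 after trimmed-mean scaling (camera adjusted p = 0.88), with 11 genes higher and 10 lower. Of the 21 genes 5 had an unadjusted limma p under 0.05, against 2560 of all 12257 tested genes. Immediate early genes had 3 such genes, Ier2 (0.57), Jund (0.78) and Junb (0.76), among 21 (16 higher, median 0.17, camera adjusted p = 0.76). The immediate early list lay above other genes without vehicle 1 (median 0.31, camera adjusted p = 0.027), but with an estimated correlation its adjusted p = 0.96. After removal of the GC trend, Bbc3, Ier2 and Jund had log2 changes of -0.04, 0.12 and 0.13, and Bcl2l1 and Sesn2 of 0.52 and 0.19. Leaving out vehicle 1 let 3 genes pass over all genes in each of the p53, immediate early and hypoxia lists, and none of them when the GC trend was removed as well. Of 30 proliferation genes 26 were higher (median 0.11, camera adjusted p = 0.98; 0 passed over the list alone). Vehicle 1 was low in all 30 of them, by a median of -0.95 log2 units against the mean of vehicle 2 and 3. Without vehicle 1 the list had a median of -0.14 and lay below other genes by a mean of -0.20 (camera adjusted p = 0.0039), and with an estimated correlation its adjusted p = 0.96.

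Metabolic lists had medians above 0 and did not pass. Of 22 hypoxia and glycolysis genes 17 were higher (median 0.20, camera adjusted p = 0.53), and 3 passed when adjusted over the list alone, of which the lactate transporter gene Slc16a3 had the smallest p (1.44 ± 0.272 to 2.93 ± 0.261 FPKM, SD, n = 3 each). The glucose transporter gene Slc2a1 had a log2 change of 0.57 and Ldha, which encodes lactate dehydrogenase A, of 0.38. The list passed without vehicle 1 (camera adjusted p = 0.00066) and after quantile normalization (0.031), but with an estimated correlation its adjusted p = 0.92 and 0.88. Srebf1 and Srebf2, the regulators of fatty acid and cholesterol synthesis, passed over their list alone (log2 changes 0.75 and 0.54) among 21 genes, of which 16 were higher (median 0.18, camera adjusted p = 0.76). Nuclear-encoded oxidative phosphorylation genes had a median of 0.26 over 23 genes, 14 of them higher, but Uqcrb was lower when adjusted over the list alone; camera gave the opposite direction to the median (adjusted p = 0.88). Ribosomal protein genes were higher for 18 of 24 (median 0.26, camera adjusted p = 0.53; 0 passed over the list alone), and they passed after quantile normalization together with the collagens (adjusted p = 0.031 for both, and 0.88 with an estimated correlation). Without vehicle 1 the medians were 0.07 for ribosomal proteins, 0.07 for oxidative phosphorylation and 0.06 for cholesterol and fatty acid synthesis. After removal of the GC trend, Srebf1, Srebf2, Slc16a3, Slc2a1 and Ldha had log2 changes of 0.38, 0.19, 0.38, 0.34 and 0.24.

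The remaining response lists had no member that passed when adjusted over the list alone. Of 22 unfolded protein response genes 15 were higher (median 0.15, camera adjusted p = 0.76), with Trib3 and Chac1, targets of ATF4, at log2 changes of 0.79 and 0.81. Of 25 interferon response genes 23 were higher (median 0.13, camera adjusted p = 0.61), with Bst2 at 0.56, Oas2 at 0.41 and Irf7 at 0.39. The interferon median was 0.02 without vehicle 1. After removal of the GC trend Bst2, Oas2 and Irf7 had log2 changes of 0.29, 0.29 and 0.12, and Trib3 and Chac1 of 0.43 and 0.47. Of 22 inflammatory cytokines and NF-κB targets 14 were higher (median 0.09, or -0.04 after trimmed-mean scaling), while their mean lay below that of other genes (camera adjusted p = 0.88); the growth factor gene Csf2 had a log2 change of -0.82 and Lif of 0.35. The Nrf2 and xenobiotic response list had a median of 0.07 (-0.01 after trimmed-mean scaling) over 15 genes, 10 of them higher, and likewise a mean below that of other genes (camera adjusted p = 0.98). Its median was 0.03 without vehicle 1.

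Cell type markers were compared to see whether the makeup of the samples differed. Macrophage markers were higher in ITSN for 16 of 18 genes (median log2 change 0.35, camera adjusted p = 0.76), but the integrin gene Itgam was lower and passed when adjusted over the list alone (14.2 ± 4.04 to 6.81 ± 0.566 FPKM, SD, n = 3 each, limma adjusted p over all genes = 0.085). An overlapping second ID that the table also names Itgam went the other way, from 3.20 ± 2.27 to 14.2 ± 3.61 FPKM, so the value depends on how reads were split between them. The complement gene C1qc had a log2 change of 0.90 and Cd14 of 0.61. Neutrophil markers had the smallest camera p of the 30 lists tested (0.016, camera adjusted p = 0.48), with 9 of 13 lower and a median of -0.26, among them Lcn2 (-0.88) and Mmp8 (-0.55). Fibroblast markers were higher for 10 of 12 genes (median 0.37, camera adjusted p = 0.83) and antigen presentation genes for 8 of 9 (median 0.34, camera adjusted p = 0.61), with Fscn1 passing over the list alone (0.61). Among 6 T and NK cell markers, the perforin gene Prf1 passed over the list alone (2.47 ± 0.532 to 4.78 ± 0.422 FPKM, SD, n = 3 each) and the list median was 0.10, or -0.02 after quantile normalization (camera adjusted p = 0.76).

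Vehicle 1 differed from the other vehicle libraries in these markers. Against the mean of vehicle 2 and 3 it had a median of -1.33 log2 units for fibroblast markers (11 of 12 lower), -1.13 for macrophage markers (18 of 18 lower) and 0.96 for neutrophil markers (3 of 13 lower), where all tested genes had a median of -0.18. Without vehicle 1 the medians between ITSN and vehicle were -0.03 for fibroblast markers, -0.07 for macrophage markers and -0.06 for neutrophil markers. Antigen presentation genes were lower in vehicle 1 for 9 of 9 members, by a median of -0.79, and without it their median between ITSN and vehicle was 0.05. The medians of T and NK cell, endothelial and pericyte markers turned to -0.03, 0.05 and -0.05 without vehicle 1. After removal of the GC trend Fscn1 had a log2 change of 0.18, Prf1 of 0.53 and C1qc of 0.56.

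The other cell type lists did not pass either, with camera adjusted p from 0.53 to 0.98 and no member passing over the list alone. Endothelial markers had a median log2 change of -0.09 over 13 genes, pericyte and smooth muscle markers of 0.02 over 6 (-0.06 after trimmed-mean scaling), Schwann cell and nerve markers of 0.30 over 3, white adipocyte markers of 0.51 over 7, mammary secretory markers of -0.12 over 5, keratinocyte and hair follicle markers of -0.12 over 3, and erythroid markers of 0.13 over 5, where camera gave the opposite direction to the median. Without vehicle 1 the medians of white adipocyte, mammary secretory, keratinocyte and erythroid markers were 0.26, -0.03, -0.45 and 0.33. Of 20 white adipocyte markers 7 were tested, without Adipoq, Plin1 and Pparg. Of 17 mammary secretory markers 5 were tested, without Csn2, Wap and Lalba. The medians of these 2 lists therefore do not measure the content of such cells. Brown adipocyte markers, with 2 genes tested, were not tested as a list. Skeletal muscle markers were higher for 7 of 7 tested genes (median 0.51, camera adjusted p = 0.53). Tpm2, with the smallest p of them, was higher in all 3 ITSN libraries, at 4.10, 4.85 and 4.03 FPKM in ITSN 1, 2 and 3 and at 2.07, 2.55 and 3.75 FPKM in vehicle 1, 2 and 3. The muscle actin gene Acta1 was at 8.76, 20.9 and 0.0521 FPKM in ITSN 1, 2 and 3 and at 0.00615, 0.937 and 1.23 FPKM in vehicle 1, 2 and 3.

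With the preset correlation, camera passed 0 of the 30 lists, and 2 (neutrophil markers, hypoxia and glycolysis) had an unadjusted p under 0.05. With an estimated correlation between genes, it passed none of them either (adjusted p = 0.9965 for each), and the fry test of whether a list moves one way passed none (adjusted p from 0.15 to 0.98). Camera with an estimated correlation also passed no list in any of the 10 splits of the libraries, where the preset correlation gave up to 18. Whether it can pass a list with so few libraries was not checked. A call lost with it, here or elsewhere in the text, is therefore not shown to be false. The fry test had a second form. The fry test of change in either direction passed 7 lists: TGF-β pathway components (adjusted p = 0.00037), TGF-β target genes (0.018), epithelial markers (0.0013), p53 targets and apoptosis (0.0022), immediate early genes (0.016), cholesterol and fatty acid synthesis (0.018) and oxidative phosphorylation (0.030). Neither fry test compares a list with other genes. In data simulated with the spread of these 6 libraries, limma recovered 82.1% of genes changed by 1 log2 unit and 11.9% of those changed by 0.5. The changed genes were drawn from the more abundant ones, and the noise was independent, with no outlying library and no GC trend. These shares therefore do not give the power for low genes or for the libraries as they are.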

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

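The 24 genes named for their change kept their direction in the settings tabulated for them, but they were chosen for groups that do not overlap, so a left-out library or a block could not turn it. The GC removal, the dropping of mitochondrial genes and the settings that leave out 2 libraries or combine 2 choices were chosen after the result was seen. The count of 7 genes became 19 with a filter of 5 FPKM, 108 after trimmed-mean scaling, 93 after quantile normalization, 48 at an unadjusted p under 0.05 with a 2-fold change, 158 after mitochondrial and ribosomal RNA region genes were dropped, 2 without vehicle 2 and ITSN 1 (Ccnb1ip1 and Zfp281, neither among the 7), 59 (19 higher, 40 lower) without vehicle 1 and the GC trend, and 1 to 673 with each library left out. Array weights gave 9734 genes, but limma reported that the estimation did not converge (weight 1054 for vehicle 2, under 0.1 for vehicle 1 and 3). A gene-by-gene estimate gave 6132 genes with weights of 6.01 for vehicle 2 and 6.21 for ITSN 1, the libraries that lie between the others of their group and so leave small residuals, and neither count is interpretable. In the fit of 9734 genes Tgfbr1 passed at -0.069 (adjusted p = 0.0056; over the alternatives 0.0056 to 0.96), and Vim and Zeb1 turned to -0.10 and 0.20. The replicate number as a block gave 2 genes and 1 list (neutrophil markers, lower, lost with an estimated correlation at adjusted p = 0.94). Deviations of libraries with the same number correlated at -0.00, -0.14 and 0.24, and not every library correlated best with its own number. With 3 libraries per group such correlations can neither show nor exclude a pairing. The labels' protocols name 6 separate mice and no pairs, and the number of ITSN 3 differs between its title and its description. The count of 0 lists became 1 without a filter (skeletal muscle), 3 after quantile normalization and 1 without vehicle 2 and ITSN 1 (neutrophil markers). It was 2 without vehicle 1 and the GC trend, and 0 to 4 with each library left out. Each of these calls was lost with an estimated correlation. That form of camera called no list in any of the 10 splits either, so the losses do not show the calls to be false. Proliferation, 0.05 above other genes with all 6 libraries, ran from -0.20 (without vehicle 1) to 0.22 with each library left out, and was -0.19 without vehicle 1 and the GC trend. Changes of sign with no call on either side are counted as no change (30 of 678 gene values, 59 of 595 list values). Leaving out a library leaves 2 against 3 mice. Causes were tested for vehicle 1 and GC content only (see the other observations); for the other settings the cause was not tested. Depth is unknown and sets no stated limit.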

Other observations

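The tests of the library mixture, of stromal cells in vehicle 1 and of GC content as the whole cause of the calls were chosen only after the result was seen. The other tests were written down before.

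Wwtr1 encodes TAZ, and a higher level of TAZ may raise its target genes. Of 19 YAP and TAZ targets 15 were higher and 4 lower in ITSN (median log2 change 0.09). No shift against other genes was found (camera with an estimated correlation, two-sided p = 0.596). That form of camera called none of the gene lists with all 6 libraries, so the hypothesis stays open. Members differed: Ajuba was at 3.27 ± 0.506 FPKM in vehicle and 6.48 ± 0.801 FPKM in ITSN (log2 change 0.81, or 0.45 after GC removal, limma adjusted p = 0.072), Amotl2, Nuak2 and Cyr61 had log2 changes of 0.65, 0.49 and 0.29 (0.34, 0.25 and 0.10 after GC removal), Asap1 of -0.22 (-0.29), and Ctgf was at 21.9 ± 1.32 and 22.6 ± 4.17 FPKM (SD, n = 3 each), none passing limma's threshold. Gpx1 is a selenoprotein, and its mRNA is known to fall when selenium is short. The other 19 selenoprotein genes could then be lower too, but 14 were higher and 5 lower (camera with an estimated correlation, two-sided p = 0.567), which does not decide the question.

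In both groups 1 library lay between the other 2, as a blend of them would: in ITSN 1, 2 and 3 the muscle genes Myh4 and Ttn were at 9.39, 20.9 and 0.0142 and at 3.79, 8.25 and 0.114 FPKM, while Col1a1, highest in ITSN 3, was at 63.8, 38.0 and 85.1 FPKM. Vehicle 2 lay between vehicle 1 and 3 for 95.6% of the 804 genes that differed at least 2-fold, at a median of 0.319 of the way to vehicle 1 (interquartile range 0.264 to 0.391), and ITSN 1 between ITSN 2 and 3 for 85.4% of 157 genes, at 0.433; over all tested genes their shares of 73.2% and 63.7% were the highest of the 60 ways to set 1 library between 2 others. Shared or mixed material needs the same fraction for every gene group: the medians of 8 groups in ITSN ran from 0.421 to 0.528 and those of 23 groups in vehicle from 0.243 to 0.544, a range of 0.3005. Its upper end, the unfolded protein response, has a bootstrap SE of 0.152, so the range does not decide. Ribosomal proteins at 0.243 (SE 0.0146) lay below mitochondrially encoded genes at 0.335 (SE 0.0123) by more than their SE. This pair was picked from the 23 groups after their medians were seen. Such groups may also share noise within a library, which was not tested. Mixing and a gradient of tissue composition therefore cannot be told apart. A gradient could give mitochondrial and collagen genes different fractions, but these differed by 0.0187 (SE 0.0144), which both explanations allow; if material was shared, vehicle 2 and ITSN 1 are not independent replicates, and without them 585 genes had an unadjusted p under 0.05, where the 8 other fits of 2 against 2 had 684 to 3951, but leaving out a middle library widens the spread with or without mixing.

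The trend of fold change with GC content was found within families of genes that are usually regulated together. The slope over all tested genes was 0.24 log2 units per 10 points of GC, and it was 0.23 in 80 cytosolic ribosomal protein genes, 0.17 in 78 mitochondrial ribosomal protein genes, 0.34 in 38 proteasome genes and 0.20 in 36 complex I genes, a median of 0.9106 of the slope over all genes. This is consistent with GC-dependent recovery of fragments that differed between the groups, by a test that could have come out the other way. GC content is argued against as the whole cause of the called genes, since 4 of the 7 still passed after its removal. An effect of ITSN that follows GC content was not tested apart from this, as no batch label separates preparation from treatment.

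The count of called genes was 7 with vehicle 1 and 673 without it. Fewer stromal cells in this library may contribute, since its fibroblast markers lay lower by a median log2 of -1.333, of which collagen genes such as Col1a1 (12.3 FPKM, against 48.3 and 66.4 in vehicle 2 and 3) are part. Other stromal lists did not fall alike: endothelial markers lay at 0.04 (4 of 13 lower) and pericyte and smooth muscle markers at -0.23 (5 of 6 lower). Among stromal lists the fall was thus seen for fibroblast and matrix genes and not for all cell types. It was not particular to stroma. Macrophage markers lay at -1.13 (18 of 18 lower) and antigen presentation genes at -0.79 (9 of 9 lower). Skeletal muscle markers lay at -0.99 (7 of 7 lower) and ribosomal proteins at -0.53 (22 of 24 lower). Neutrophil and epithelial markers lay higher, at 0.96 (3 of 13 lower) and 0.15 (5 of 13 lower). Stroma as the whole difference is argued against by the proliferation genes, which are not stromal markers and lay lower by -0.9472, where all tested genes had a median of -0.18. Scaling by mitochondrial and ribosomal RNA region transcripts stays open, as dropping these genes raised the count with all 6 libraries to 158, between the bounds set for and against it. Damage to the tissue or RNA of this mouse was not tested.

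Of the 10 splits of the 6 libraries into 3 and 3, the real one called 7 genes and the highest other called 1, so the count was matched in 1 split, the real one. The real split called 0 lists, a count that all 10 splits match whatever the data, so it tests nothing. The highest other split called 18 lists at the preset correlation, but with an estimated correlation none of the 10 splits called a list (lowest adjusted p = 0.359). With 10 splits no share can fall under 0.05.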
